A study of Mus musculus with 8 samples.

How the data were processed

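The series holds 8 RNA-seq libraries from C57BL/6 mice, 4 labelled KO and 4 labelled Control. Per the labels, KO mice carried Otp-Cre, homozygous floxed Cic and the ROSAfsTRAP allele, and Control mice carried Otp-Cre and ROSAfsTRAP alone. Otp-Cre directs recombination to cells of the Otp lineage, and the Cre-dependent TRAP allele tags ribosomes so that the RNA bound to them can be purified (translating ribosome affinity purification). Hypothalamus and medial amygdala were dissected and the purified RNA was amplified to cDNA from 10 ng with a NuGEN Ovation kit that primes at poly(A) tails and at random, sheared, made into Illumina TruSeq DNA libraries and sequenced on a HiSeq system, per the labels' protocols. Purification can leave RNA of other cells in the sample, and no input libraries were used here. The amplification starts from little RNA and the counts carry no molecular identifiers, so amplified copies of 1 molecule cannot be told from separate molecules, and intervals or spreads from counts cover counting and sample error together. Library conversion from double-stranded cDNA does not mark strand, and the strand setting of the counting is not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart.

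The deposited values are raw read counts per gene symbol, one table per library, made by the authors with TopHat2 2.0.9 and HTSeq on mm10, per the submitters' processing notes; these also name DESeq2, and its version, the HTSeq version, the gene annotation and any filter are not given in the sources used here. Each table held 24421 gene rows, 92 ERCC spike-in rows and 5 HTSeq counter rows. The spike-in and counter rows were left out of library sizes and tests. Spike-ins amounted to 0.148% ± 0.165 of gene counts in KO and 0.387% ± 0.0997 in Control (mean ± SD, n = 4 each, exact two-sided permutation p = 0.0857). Of all counted records, 74.9% ± 5.35 in KO and 70.2% ± 4.77 in Control were alignments that were not unique (exact permutation p = 0.286), 8.29% ± 0.309 and 8.71% ± 0.200 lay in no annotated feature (exact permutation p = 0.0857), and 0.410% ± 0.123 and 0.519% ± 0.127 were ambiguous (exact permutation p = 0.314). The ribosomal RNA row Rn45s took 7.85% ± 2.41 of gene counts in KO and 9.81% ± 1.35 in Control (exact permutation p = 0.229). HTSeq drops reads that align to several places, so genes with near-identical copies are undercounted.

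Gene counts per library ran from 33223878 to 49587839 in KO and from 38171319 to 57300362 in Control. Over 28 pairs of libraries the chi-square per degree of freedom of the counts was 25.9 or more, far above the value of 1 that sampling noise gives, so no library repeats another. The labels number the replicates and do not say whether each came from 1 animal, so p-values measure the spread between these samples. Shared replicate numbers are not stated to pair mice, so the main fit had no replicate block, which was run as an alternative. Deviations of same-numbered KO and Control libraries from their group means correlated at -0.05 to 0.1.

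Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, and a robust quasi-likelihood fit of KO against Control over all 8 libraries with no covariate. Log2 fold changes are KO over Control from that fit, "edgeR adjusted p" stands for the quasi-likelihood p with Benjamini-Hochberg adjustment over all genes tested, and the threshold was 0.05. CPM values are counts scaled to library size with TMM factors, given as mean ± SD of 4 libraries. SE is the standard error of the difference of the group means of log2 CPM. Single values were compared with exact two-sided permutation tests, which with 4 against 4 cannot go below 0.029. The model was tested on simulated counts for the same 15438 genes and library sizes with 200 changed genes. At 1.5-fold it recovered 20 of 50, at 2-fold 34 of 50, at 3-fold 40 of 50 and at 4-fold 41 of 50, with 5 false calls among 15238 unchanged genes. A change of 1.5-fold is thus missed more often than found at this depth and spread, and the biological coefficient of variation was 0.241.

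Before the data were examined, 41 gene lists (the CIC complex and targets of CIC known from other systems, hypothalamic lineage, peptide and receptor genes, synaptic and channel genes, signalling and stress genes, and markers of other cell types and regions) and the naming rule were fixed. Lists with 5 or more tested members were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, with Benjamini-Hochberg adjustment over lists. "Adjusted over the list alone" means Benjamini-Hochberg over that list's members only. The text names Cic, Atxn1, Atxn1l, Otp, Sim1, Avp, Oxt, Crh, Trh, Sst, Etv1, Etv4, Etv5, Spry4 and Dusp6 always, then, among genes past the threshold with no overlap between groups, a mean of at least 1 CPM and a symbol that is not a clone or predicted name, the 12 with the largest rise and the 12 with the largest fall (10 in all), and for each list up to 4 members past the threshold or, with none, the 2 with the smallest p. Other members of lists and other genes named were chosen after their values were seen.

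Positions, strand and overlaps came from GENCODE mouse release 21 on GRCm38, the assembly also called mm10; 24054 of the 24421 gene rows (98.5%) matched, 23384 by symbol and 670 by an older symbol. The alternatives were DESeq2 size factors, upper-quartile scaling and total counts; no filter and a stricter filter; DESeq2 1.42.0, limma-voom with and without quality weights, and a fit that was not robust; a replicate block; a surrogate variable (sva 3.50.0); a glial and vascular score or Xist as covariate; removal of ribosomal protein and haemoglobin genes (105 rows); a GC and length offset (99.2% of tested genes had both); other thresholds; and each library left out in turn. Keeping the ERCC rows and removing Rn45s and Lars2 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.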

Results

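RNA bound to ribosomes of Otp-lineage cells was measured in mice with and without a floxed Cic allele, to ask how loss of Cic, which encodes the DNA-binding repressor Capicua, partner of ATXN1, changes gene expression in these neurons. The Otp lineage includes neuroendocrine neurons of the hypothalamus and neurons of the medial amygdala. The 4 KO libraries held 33223878 to 49587839 gene counts (mean 41460000 ± 6705000 SD) and the 4 Control libraries 38171319 to 57300362 (45540000 ± 8211000, n = 4 each, exact permutation p = 0.514). The number of genes with counts was 17050 ± 269 in KO and 17410 ± 235 in Control (n = 4 each, exact permutation p = 0.171).

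Cic was lower in every KO library than in any Control library. It measured 34.5 to 59.3 CPM in KO and 72.4 to 103 CPM in Control, where replicate 2 at 72.4 CPM lay below the other 3 libraries. The means were 44.0 ± 11.04 and 94.2 ± 14.6 CPM (n = 4 each), so KO held 46.7% of the Control level (log2 fold change -1.10, SE 0.21, edgeR adjusted p = 0.00220, exact permutation p = 0.0286, the smallest this design allows is 0.029). Cic (ENSMUSG00000005442.13) lies on chromosome 7 from 25267704 to 25294159 on the plus strand of GRCm38. Counts covered the whole gene, so transcript outside the deleted part and RNA of other cells can both be counted. The other members of the ATXN1-CIC complex and its co-repressors did not pass the test. Atxn1 had 195 ± 49.1 CPM in KO and 169 ± 7.81 in Control (log2 fold change 0.20, edgeR adjusted p = 0.709), and Atxn1l had 37.0 ± 9.82 and 37.5 ± 1.08 CPM (log2 fold change -0.02, edgeR adjusted p = 0.982). For the list of 8 genes the median was 0.14, the mean -0.05 and the camera direction down, which differ in sign because Cic alone fell (camera adjusted p = 0.881).

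Of 15438 genes tested, 40 passed edgeR adjusted p 0.05, 30 higher and 10 lower in KO, and 38 of the 40 had no overlap between the groups. Among all tested genes 5.9% had no overlap against 2.9% given by chance. At an unadjusted p of 0.05, 1634 genes passed. Of the 26 called genes that the naming rule covers, those that rose most were Fndc3c1 (log2 fold change 2.31, SE 0.56, with KO replicate 2 at 13.04 CPM against 2.30 to 4.13 in the other KO libraries), Etv4 (2.24, SE 0.27), Omp (2.05, SE 0.33), Hcrtr1 (1.97, SE 0.20), Maff (1.91, SE 0.33) and Clca3a1 (1.77, SE 0.30). Next came Spry4 (1.39), Proser3 (1.38), Pgr15l (1.30), Etv5 (1.29), Spred3 (1.27) and Dusp4 (1.22). The genes that fell were Cic (-1.10), Gjb1 (-1.09), Pllp (-0.98), Sstr3 (-0.90), Cldn11 (-0.81), Rnf141 (-0.72), Smox (-0.71), Leprot (-0.70), Gatm (-0.68) and Desi1 (-0.58). Leaving out 1 library moved the count to between 14 and 53. It was 26 without KO replicate 2, 19 without Control replicate 1, 17 without Control replicate 2, 26 without Control replicate 3 and 14 without Control replicate 4.

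**Figure D1:**
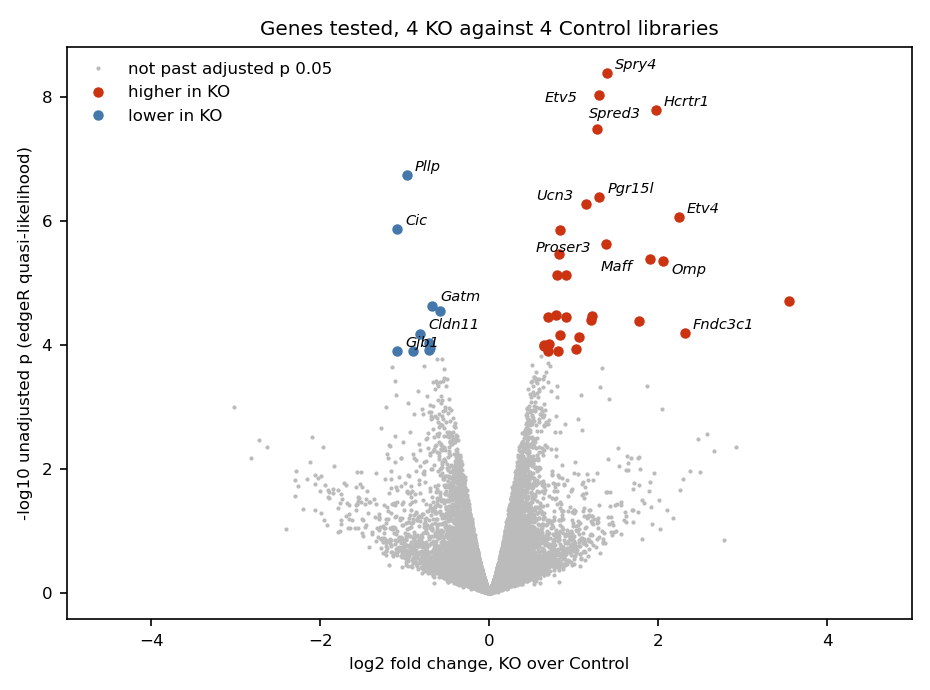
Each point is 1 of 15438 genes, with the log2 fold change of KO over Control on the x axis and -log10 of the unadjusted edgeR quasi-likelihood p on the y axis. Red points are the 30 genes higher and blue points the 10 genes lower in KO at edgeR adjusted p 0.05.

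Genes known from other systems to be repressed by Capicua were higher in KO as a group. Of the 20 on the list 19 were tested, 16 had a positive and 3 a negative fold change, 6 rose over all genes tested and 0 fell, and 13 rose and 0 fell adjusted over the list alone. The median log2 fold change was 0.50 (camera adjusted p = 1.74e-15, and adjusted p = 0.0109 with an estimated correlation). The 3 negative ones were Etv1, Spry1 and Spry2.

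The ETS transcription factor Etv4 went from 1.195 ± 0.438 to 5.62 ± 0.595 CPM (log2 fold change 2.24, SE 0.27, edgeR adjusted p = 0.00169), and its relative Etv5 from 30.6 ± 4.62 to 75.0 ± 9.99 CPM (1.29, SE 0.14, edgeR adjusted p = 7.38e-05). Of the genes that dampen receptor tyrosine kinase and ERK signalling, Spry4 (Sprouty 4) went from 26.4 ± 5.20 to 69.1 ± 2.84 CPM (1.39, SE 0.15, edgeR adjusted p = 6.42e-05), Spred3 from 40.0 ± 2.42 to 96.7 ± 21.4 CPM (1.27, SE 0.17, edgeR adjusted p = 0.000127) and the MAP kinase phosphatase Dusp4 from 4.08 ± 0.283 to 9.50 ± 2.65 CPM (1.22, SE 0.20, edgeR adjusted p = 0.0238). Maff, a small Maf transcription factor, went from 2.09 ± 0.771 to 7.82 ± 2.75 CPM (1.91, SE 0.33, edgeR adjusted p = 0.00484), with Control replicate 2 at 3.25 CPM above the other 3. Spred2 (0.52), Shc4 (1.08), Shc3 (0.43), Spred1 (0.36), Ptpn9 (0.32), Ccnd1 (0.31) and Gpr3 (0.50) passed only when adjusted over the list alone. Among the targets that did not pass, Etv1 had 85.5 ± 10.6 CPM in KO and 90.0 ± 21.8 in Control (log2 fold change -0.07, SE 0.19, edgeR adjusted p = 0.911). Dusp6 had 12.8 ± 3.70 and 12.2 ± 3.05 CPM (0.07, SE 0.31, edgeR adjusted p = 0.950), with Control replicate 2 low at 7.69 CPM. Spry2 had 37.7 ± 12.4 and 38.2 ± 3.12 CPM (-0.02, edgeR adjusted p = 0.982). Genes of the ERK cascade itself did not move together (9 positive and 9 negative, median 0.02, camera adjusted p = 0.633), with Sos1 at 0.39 and Ksr1 at -0.52 as the members of smallest p. Dusp4 passed in 2 of the 8 fits that left out 1 library, whereas Etv4, Etv5, Spry4, Spred3 and Maff passed in all 8.

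On GRCm38, Etv4 (ENSMUSG00000017724.14) lies on chromosome 11 from 101769742 to 101785371, Etv5 (ENSMUSG00000013089.15) on chromosome 16 from 22381309 to 22439719 and Spry4 (ENSMUSG00000024427.7) on chromosome 18 from 38586247 to 38601415. Spred3 (ENSMUSG00000037239.8) lies on chromosome 7 from 29158829 to 29170411 and overlaps Ggn on the opposite strand, whose reads cannot be told from its own. Spred3 is also within 10 Mb of Cic, and only KO mice carried the floxed Cic allele. For Spred3, DNA linked to that allele thus cannot be told apart from loss of Cic. Dusp4 (ENSMUSG00000031530.6) lies on chromosome 8 from 34807297 to 34819894 and Maff (ENSMUSG00000042622.14) on chromosome 15 from 79346621 to 79359076.

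**Figure D2:**
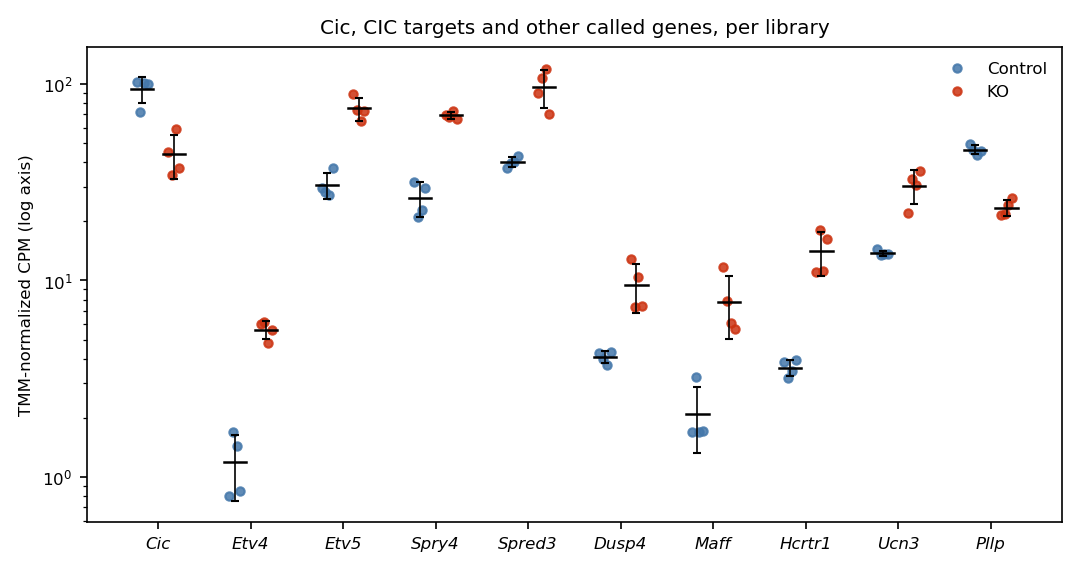
CPM with TMM scaling (log axis) are drawn per library for Cic, 6 CIC targets, Hcrtr1, Ucn3 and Pllp, with Control in blue and KO in red, the bar marking the mean and the whiskers the SD of 4 libraries. The groups did not overlap for any gene drawn, and Cic measured 44.0 CPM in KO against 94.2 in Control.

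Among genes of peptide signalling, the orexin receptor Hcrtr1 rose 3.91-fold, from 3.61 ± 0.351 to 14.1 ± 3.57 CPM (log2 fold change 1.97, SE 0.20, edgeR adjusted p = 8.54e-05). It lies on chromosome 4 from 130130217 to 130139359 (ENSMUSG00000028778.15). Ucn3, which encodes the stress peptide urocortin 3, rose 2.21-fold, from 13.8 ± 0.422 to 30.4 ± 5.98 CPM (1.14, SE 0.16, edgeR adjusted p = 0.00119), on chromosome 13 from 3940688 to 3945349 (ENSMUSG00000044988.7). Sstr3, a somatostatin receptor of neuronal cilia, fell from 17.1 ± 1.48 to 9.10 ± 2.44 CPM (-0.90, SE 0.21, edgeR adjusted p = 0.0489). Of 34 neuropeptide and hormone receptors 1 rose, 1 fell and 32 did not pass, and 28 had a positive fold change (3 rose and 1 fell adjusted over the list alone; median 0.16; camera adjusted p = 0.00673, adjusted p = 0.866 with an estimated correlation). Besides Hcrtr1, which passed over all genes, the receptors Calcr (0.71) and Cckar (0.65) rose, and only when adjusted over the list alone. The list lost its call without Control replicate 4 (camera adjusted p = 0.0510) and with the glial and vascular covariate (0.136).

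The 28 tested hypothalamic neuropeptides had no common direction, with 1 rise (Ucn3, also the only 1 adjusted over the list alone), 0 falls and 27 that did not pass (median -0.01, mean 0.16, camera direction up, camera adjusted p = 0.395), though the list passed, upward, with the glial and vascular covariate (median 0.07, camera adjusted p = 0.0360). Oxt, oxytocin, had 317 ± 132 CPM in KO and 189 ± 22.2 in Control (log2 fold change 0.75, SE 0.35, edgeR adjusted p = 0.342, and 0.0114 without KO replicate 3, with a range of 0.0114 to 0.648 over all alternatives). Avp, vasopressin, had 329 ± 108 and 244 ± 21.5 CPM (0.43, SE 0.24, edgeR adjusted p = 0.373). Sst had 727 ± 244 and 509 ± 75.2 CPM (0.51, edgeR adjusted p = 0.342), and Trh 43.4 ± 8.46 and 31.5 ± 5.42 CPM (0.46, edgeR adjusted p = 0.274). Crh was low in both groups, with 2.34 ± 0.988 and 1.84 ± 0.629 CPM (0.35, edgeR adjusted p = 0.825). Genes of peptide processing and dense-core granules did not move together (median 0.01, camera adjusted p = 0.395), with Vgf at 0.70 (edgeR adjusted p = 0.0684, past 0.05 adjusted over the list alone, and past it over all genes in 8 alternatives, with a range of 0.00669 to 0.306 over all of them) and Scg3 at 0.27.

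Transcription factors that mark the Otp lineage were all on the positive side, 6 of 6, with a median log2 fold change of 0.47, but 0 passed over all genes and 2 did adjusted over the list alone (camera adjusted p = 0.00589, adjusted p = 0.835 with an estimated correlation). Sim1 had 22.4 ± 6.81 CPM in KO and 14.4 ± 3.45 in Control (0.65, SE 0.27, edgeR adjusted p = 0.228) and Nhlh2 19.7 ± 2.12 and 14.5 ± 1.84 CPM (0.44, SE 0.12, edgeR adjusted p = 0.296). Otp itself was low, with 4.96 ± 2.55 and 3.45 ± 1.14 CPM (0.53, SE 0.42, edgeR adjusted p = 0.633). This list lost its call without KO replicate 1 (camera adjusted p = 0.174), without Control replicate 4 and with the glial and vascular covariate (0.182, at a median of 0.28). Imprinted genes, many of them abundant in the hypothalamus, were higher in KO, with 12 of 15 positive, 1 that rose over all genes, 7 that rose adjusted over the list alone and a median of 0.26 (camera adjusted p = 4.85e-05, adjusted p = 0.0895 with an estimated correlation). Plagl1, an imprinted zinc finger transcription factor, rose from 25.7 ± 2.44 to 48.0 ± 12.9 CPM (0.90, SE 0.23, edgeR adjusted p = 0.0238). Mest (0.59), Peg3 (0.56), Peg10 (0.52), Grb10 (0.50), Ndn (0.41) and Dlk1 (0.36) rose adjusted over the list alone. The mean list score in log2 CPM was 6.97 ± 0.0649 in KO and 6.67 ± 0.0851 in Control (exact permutation p = 0.0286 before and 0.571 after adjustment over lists).

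Axon guidance genes were positive in 21 of 27 cases, with 0 past the threshold over all genes or over the list alone and a median of 0.19 (camera adjusted p = 0.00832, adjusted p = 0.897 with an estimated correlation). Sema3a was at 0.45 and the netrin receptor gene Unc5d at 0.53. The list lost its call without Control replicate 2 (camera adjusted p = 0.0951), without KO replicate 1 and with the glial and vascular covariate (0.0670). Genes of sex steroid and corticosteroid signalling had 7 of 9 positive and a median of 0.30 (camera adjusted p = 0.0576, which did not pass, and adjusted p = 0.693 with an estimated correlation), with Esr1 at 0.61. This list passed in 7 of 28 alternatives (camera adjusted p = 0.0264 to 0.0494), among them upper-quartile scaling and total counts only.

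Of the lists of glial markers, those of oligodendrocytes, their precursors, microglia and ependymal cells were lower in KO at camera's preset correlation and none at an estimated one, and astrocyte markers did not pass. All 14 oligodendrocyte markers had a negative fold change, with a median of -0.34, and 1 fell over all genes and 6 fell adjusted over the list alone (camera adjusted p = 6.90e-10, adjusted p = 0.693 with an estimated correlation). Cldn11, the claudin of myelin tight junctions, fell from 49.2 ± 5.68 to 28.01 ± 7.56 CPM (-0.81, SE 0.20, edgeR adjusted p = 0.0375). Mag (-0.51), Mal (-0.58), Opalin (-0.65), Trf (-0.62) and Fa2h (-0.40) fell adjusted over the list alone. Mbp had 667 ± 178 and 850 ± 133 CPM, which did not pass. A further pair of myelin genes was among the 10 that fell, Pllp (plasmolipin, 46.3 ± 2.42 to 23.5 ± 2.28 CPM, edgeR adjusted p = 0.000564) and Gjb1 (connexin 32, 8.27 ± 0.787 to 3.88 ± 0.863 CPM, edgeR adjusted p = 0.0489). Pllp passed in all 8 fits that left out 1 library, whereas Gjb1 and Cldn11 passed in 1 each. Markers of oligodendrocyte precursors had a median of -0.26 with 7 of 9 negative (camera adjusted p = 0.0141), microglia -0.50 with 12 of 14 negative (camera adjusted p = 0.0120) and ependymal cells and tanycytes -0.31 with 8 of 10 negative (camera adjusted p = 0.0124), and none held with an estimated correlation (adjusted p = 0.866, 0.948 and 0.835). No member of these 3 lists passed over all genes or over the list alone. The members of smallest p were Olig1 (-0.39) and Bcas1 (-0.49), Itgam (-0.996) and C1qc (-0.64), and Col23a1 (-0.68) and Tmem212 (-0.86). Without KO replicate 1 these 3 lists lost their call, at camera adjusted p = 0.569 for precursors and 0.218 for ependymal cells. The ependymal list also lost it without Control replicate 4, and the microglia list without Control replicate 1 (0.370), Control replicate 4 and KO replicate 3, so that 4 of 8 such fits kept it. With the DESeq2 test the ependymal list lost its call, and with a surrogate variable the microglia list did. All 3 also lost it with the glial and vascular covariate, at 0.338 for precursors, 0.387 for ependymal cells and 0.871 for microglia, whose median turned to 0.18 and whose markers are part of that covariate. The oligodendrocyte list, also part of it, kept its call there at a smaller median (-0.20, camera adjusted p = 2.99e-05). Astrocyte markers (median -0.10, camera adjusted p = 0.293, Gfap at -0.31 and Aldh1l1 at -0.58) and endothelial and mural cell markers (median -0.12, camera adjusted p = 0.525, Esam at -1.14 and Acta2 at -0.55) did not pass.

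**Figure D3:**
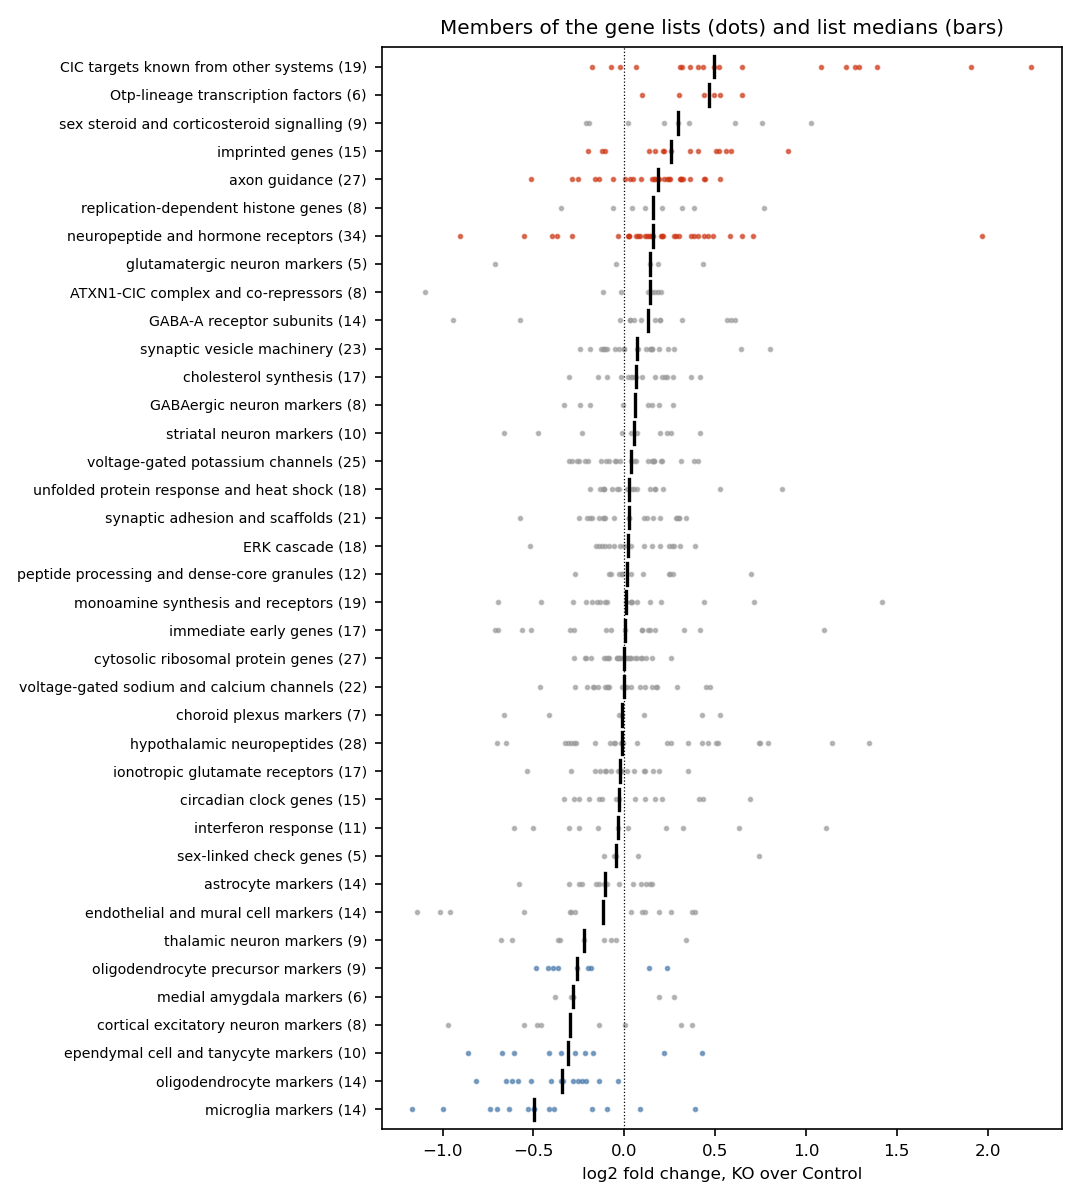
Members of the 38 tested gene lists are dots at their log2 fold change of KO over Control, with the number of tested members in brackets and a black bar at the list median. Lists past camera adjusted p 0.05 are red (up) or blue (down), from CIC targets at a median of 0.50 to microglia markers at -0.50; only CIC targets also passed with an estimated correlation.

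Of the other genes that passed, 2 synapsins of synaptic vesicles rose. Syn3 went from 38.9 ± 5.11 to 67.7 ± 8.99 CPM (0.80, SE 0.14, edgeR adjusted p = 0.00735) and Syn1 from 360.0 ± 50.5 to 562 ± 79.4 CPM (0.64, SE 0.14, edgeR adjusted p = 0.0476). Syn3 overlaps Timp3, and Syn1 overlaps Timp1 and Araf, on the opposite strand. The list of 23 vesicle genes did not pass, with the same 2 genes called over the list alone (median 0.07, camera adjusted p = 0.256). Omp, olfactory marker protein, rose from 1.45 ± 0.424 to 6.02 ± 2.18 CPM (edgeR adjusted p = 0.00494) and lies inside Capn5 on the same strand, so its reads are uncertain. Proser3 rose from 3.53 ± 0.285 to 9.18 ± 0.991 CPM (edgeR adjusted p = 0.00329) and overlaps Hspb6 on the opposite strand. Like Spred3, it lies within 10 Mb of Cic, so DNA linked to the floxed allele cannot be told apart from loss of Cic. The orphan receptor gene Pgr15l rose from 8.28 ± 1.86 to 20.4 ± 1.22 CPM (edgeR adjusted p = 0.00107). Fndc3c1 rose from 1.13 ± 0.191 to 5.61 ± 5.01 CPM, with a wide spread in KO (edgeR adjusted p = 0.0375), and Clca3a1 from 1.31 ± 0.381 to 4.46 ± 1.32 CPM (edgeR adjusted p = 0.0259). Gatm, an enzyme of creatine synthesis, fell from 174 ± 17.3 to 109 ± 13.0 CPM (edgeR adjusted p = 0.0199). Desi1, which overlaps Xrcc6, fell from 184 ± 7.58 to 123 ± 3.40 CPM (edgeR adjusted p = 0.0233). Smox, spermine oxidase, fell from 28.9 ± 4.40 to 17.6 ± 1.74 CPM (edgeR adjusted p = 0.0489), with Control replicate 1 low at 22.3 CPM. Leprot fell from 26.4 ± 3.55 to 16.3 ± 1.29 CPM (edgeR adjusted p = 0.0489) and Rnf141, which overlaps Ampd3, from 22.1 ± 1.03 to 13.5 ± 1.62 CPM (edgeR adjusted p = 0.0476).

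Synaptic and channel lists did not pass as groups. GABA-A receptor subunits were positive in 11 of 14 cases (median 0.13, camera adjusted p = 0.107). Over the list alone Gabrg3 (0.61) and Gabrq (0.59) rose while Gabra4 (-0.57) and Gabrd (-0.94) fell. Ionotropic glutamate receptors had a median of -0.03 (camera adjusted p = 0.831; Grin2c -0.53), synaptic adhesion and scaffold genes 0.02 (camera adjusted p = 0.881; Nlgn3 0.30), and Shank3 (-0.57) of that list fell adjusted over the list alone. Over all genes Shank3 passed in 3 alternatives (adjusted p from 0.0173 to 0.452 over all of them) and Gabrg3 in 1 (0.0325 to 0.396). Voltage-gated potassium channels had a median of 0.04 (camera adjusted p = 0.906; Kcnip1 0.31, Kcnc2 -0.30), and sodium and calcium channels 0.00 with a mean of 0.01 and a test direction of down (camera adjusted p = 0.934; Scn3a 0.47). GABAergic markers had a median of 0.06 and a test direction of down (camera adjusted p = 0.831; Slc32a1 -0.24, Dlx5 -0.33). Glutamatergic markers had a median of 0.14 (camera adjusted p = 0.913; Slc17a7 -0.71). Monoamine genes had a median of 0.01 with a test direction of down (camera adjusted p = 0.740; Htr7 -0.28, Adrb1 -0.46).

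Region and state markers did not pass either. Medial amygdala markers had a median of -0.28 (camera adjusted p = 0.633; Lhx6 -0.38, Foxp2 0.27), cortical excitatory markers -0.30 (camera adjusted p = 0.525; Rasgrf2 0.37, Neurod6 -0.97), striatal markers 0.05 with a mean of -0.02 and a test direction of up (camera adjusted p = 0.906; Rgs9 0.42, Penk 0.23) and thalamic markers -0.22 (camera adjusted p = 0.224; Calb2 0.34, Prkcd -0.62). Choroid plexus markers had a median and mean of -0.01 against a test direction of up (camera adjusted p = 0.674; Clic6 -0.41, Sostdc1 0.43). Circadian clock genes had a median of -0.03, a mean of 0.05 and a test direction of up (camera adjusted p = 0.796), and Per2 (0.69) and Cry1 (0.43) rose adjusted over the list alone, Per2 also over all genes in 4 alternatives (adjusted p from 0.0103 to 0.349 over all of them). Immediate early genes had a median of 0.01, a mean of -0.04 and a test direction of down (camera adjusted p = 0.788; Npas4 1.10, Egr1 -0.56). Cholesterol synthesis had a median of 0.07 (camera adjusted p = 0.115), and Sqle (0.42) and Fdft1 (0.37) rose adjusted over the list alone. The unfolded protein response and heat shock list had a median of 0.03 (camera adjusted p = 0.881; Hspa1a 0.87, Hsph1 0.22), and interferon genes a median of -0.04, a mean of 0.04 and a test direction of down (camera adjusted p = 0.796; Ifit1 1.11), with Ifit2 (-0.61) past 0.05 adjusted over the list alone. Ribosomal protein genes had a median of 0.00 (camera adjusted p = 0.669; Rpl10a 0.25, Rps4x -0.28) and histone genes 0.16 (camera adjusted p = 0.674; Hist2h2be 0.32, Hist1h4i 0.77). The sex-linked check genes had a median of -0.04, a mean of 0.12 and a test direction of up (camera adjusted p = 0.906; Xist 0.74, Eif2s3y -0.11). Blood cell genes had 1 tested member, Alas2 (-0.10), and pituitary hormone genes 4 (median 0.60; Cga 2.78, Tshb 1.06), too few for a set test. The list of mitochondrially encoded genes matched no row and was not analysed here. Of the lists named here, 16 changed their test direction under at least 1 alternative without passing. In all, 12 lists that did not pass in the main test did so in at least 1 alternative, most often steroid signalling (7 of 28) and thalamic markers (5 of 28).

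Of the 40 called genes 14 stayed past edgeR adjusted p 0.05 in all 8 fits that left out 1 library: Arhgap26, Cic, Etv4, Etv5, Hcrtr1, Maff, Omp, Pgr15l, Pllp, Proser3, Spred3, Spry4, Tubb2b and Ucn3. The others lost the call in at least 1 such fit, Rnf141 in all 8.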

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

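All tests of explanations in this part were chosen after the result they bear on was seen, except the split count, which was fixed before. There are 35 ways of splitting the 8 libraries into 4 and 4. The real split gave 40 genes past edgeR adjusted p 0.05, and the highest of the others gave 1. So 1 of 35 splits, the real one, gave as many, the lowest share this test can give. It argues against chance assignment of libraries for that count but cannot exclude it.

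In 7 of 228 sets of 4 libraries examined, 1 library lay apart from the other 3 by a gap past the critical value of Dixon's test, taken on log2 CPM for genes and lists and on the plain values for counts and shares per library; chance does this in about 1 in 20 sets. Cic in Control replicate 2 was low at 72.35 CPM against 100.5 to 102.8. Maff in Control replicate 2 was high at 3.246 CPM against 1.694 to 1.723, and Dusp6 in the same library was low at 7.692 CPM against 13.1 to 14.06. Smox in Control replicate 1 was low at 22.32 CPM against 30.6 to 31.9. The cortical marker Neurod6 in KO replicate 4 was high at 6.561 CPM against 3.445 to 3.489, and the choroid plexus marker Clic6 in KO replicate 1 was high at 7.668 CPM against 4.528 to 4.949. The share of spike-in counts in KO replicate 3 was 0.3946% of gene counts against 0.05686% to 0.07391% in the other KO libraries.

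The ERCC spike-ins, which were left out of the gene test of the report, differed in composition between the groups: the ratio of ERCC-00130 to ERCC-00002 was 3.886 ± 0.154 in KO and 0.524 ± 0.0428 in Control, and that of ERCC-00004 to ERCC-00003 was 1.84 ± 0.270 and 0.250 ± 0.0162 (n = 4 each). Different amounts of 1 mix are argued against, because an amount scales all spike-ins alike and the first ratio differed with an exact permutation p of 0.02857, the smallest possible. The 21 spike-ins with enough counts fell into 6 with a higher and 15 with a lower KO to Control ratio, separated by a gap of 1.224 on the log2 scale against a largest SD of 0.2441, and the class medians differed 5.34-fold. This is what 2 mixes, 1 per group, would give, though the labels do not mention them. Which mix each library received is not known, and the spike-ins were not used to scale 1 group to the other. No biological explanation was tested.

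Oligodendrocyte markers were lower in KO, with a median log2 fold change of -0.34 over 14 genes, and KO replicate 1 had the lowest list score of all libraries (5.92 in log2 CPM). Without it camera gave an adjusted p of 3.589e-05 at its preset correlation and a median of -0.22, but the exact permutation p of the list score was 0.0857, and with an estimated correlation (0.656) camera gave an adjusted p of 0.693 even with all 8 libraries, so that library alone cannot be told apart from a difference with 3 KO libraries left. The list score was 6.34 ± 0.307 in KO and 6.75 ± 0.157 in Control, an exact permutation p of 0.05714, so spread between libraries cannot be told apart from a difference with 4 libraries per group. A lower amount of RNA of all other cell types in the KO purifications may account for it: the mean score of astrocyte, microglia, endothelial and ependymal lists moved by -0.24 and the oligodendrocyte score by -0.41, and their difference had an exact permutation p of 0.4857, so the spread of the libraries keeps this open; with the glial and vascular covariate, which holds these markers too, the median was -0.20 (camera adjusted p = 2.99e-05). An effect of the genotype on myelinating cells also stays open and was not tested, since Cre acts in the Otp lineage and no input libraries were used here.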

How the results depend on the processing

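Cic stayed past the threshold in every alternative (edgeR, DESeq2 or limma adjusted p from 9.03e-08 to 0.0146), and the CIC target list passed in every one (camera adjusted p at most 0.0109). All 40 calls kept their sign wherever they were tested, and 13 stayed past adjusted p 0.05 in all 27 fits. No called gene reversed, and the microglia list, called lower, had a positive median with the glial and vascular covariate (0.18, camera adjusted p = 0.871). No scaling moved the median of all genes by over 0.1, and the share of higher calls under the scalings was 66.7% to 80.8%, against 75.0%.

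The count of 40 genes (30 higher, 10 lower) became 26 with total counts only (5 lower), 182 with DESeq2 (107 higher, 75 lower, all 40 kept, 58.8% higher) and 22 with limma-voom (17 higher, 5 lower). With Xist as covariate 30 genes passed (19 of the 40 kept), and with the glial and vascular covariate 28 (5 lower, 22 of the 40 kept). Xist was low in both groups (mean 2.41 CPM in KO, 1.44 in Control), so this covariate in part follows the group. The Y-linked gene Eif2s3y was at 9.55 to 15.3 CPM in every library. Calls lost with the Xist covariate can thus not be read as an effect of sex. Genes lower numbered 6 in the fit that was not robust and 5 with a surrogate variable. With the GC and length offset 64 genes passed (47 higher, 17 lower, all 40 kept). At adjusted p 0.1 it was 82 (56 higher, 26 lower), the larger count coming from the looser threshold; the cause of the others was not tested. With each library left out the counts ran from 14 to 53 in all, 12 to 36 higher and 2 to 17 lower, with fewer samples in the fit. They were 26 without KO replicate 2, 19, 17, 26 and 14 without Control replicates 1, 2, 3 and 4, and 53 without KO replicate 4.

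Of the 9 lists, 1 passed with an estimated correlation and 1 with fry, CIC targets in both. With the glial and vascular covariate 4 passed, 3 of them among the 9 (CIC targets, imprinted genes and oligodendrocyte markers) and hypothalamic neuropeptides, and with Xist as covariate 15, all 9 included. Without 1 library the count was 4 to 13, lowest without KO replicate 1 and highest without Control replicate 3. The fold change minimum of 1.5 gave 39 genes and no separate value for lists or single genes.

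The labels do not say whether the replicate number pairs the samples. Deviations from the group means of same-numbered libraries correlated at -0.05, -0.05, 0.00 and 0.10, and only replicate 4 correlated best with its own number. These few values cannot settle whether the samples were paired. The replicate block gave 65 genes (43 higher, 22 lower, 39 of the 40 kept), and with the GC and length offset as well 60 (41 higher, 19 lower). Keeping the ERCC spike-ins gave 36 genes and removing Rn45s and Lars2 gave 40, both chosen after seeing the data. Among named genes, 146 values of 16 called genes fell short of the threshold and 21 values of uncalled genes passed it. At this depth and spread 20 of 50 simulated 1.5-fold changes were found.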

Other observations

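The test of overlapping neighbours in this part was chosen before its result was seen, the other tests after. Of the 40 called genes, 14 fell outside the naming rule, and they were chosen here after their values were seen; all 14 were higher in KO. Hsd11b1, the enzyme that regenerates active glucocorticoid, rose from 7.96 ± 1.87 to 18.4 ± 6.26 CPM (edgeR adjusted p = 0.0253), and Prlr, the prolactin receptor, from 14.5 ± 2.61 to 25.8 ± 4.16 CPM (edgeR adjusted p = 0.0384). The calcium/calmodulin kinase gene Camk1g rose from 19.5 ± 2.52 to 36.4 ± 6.36 CPM (edgeR adjusted p = 0.00735), the bicarbonate transporter gene Slc4a8 from 54.7 ± 9.86 to 88.3 ± 15.6 CPM (edgeR adjusted p = 0.0489) and Marcks, a substrate of protein kinase C, from 68.5 ± 6.18 to 107 ± 18.9 CPM (edgeR adjusted p = 0.0489). Tubb2b, a beta tubulin with close paralogs that can share its reads, rose from 26.8 ± 1.94 to 47.9 ± 3.84 CPM (edgeR adjusted p = 0.00220), and Arhgap26 from 88.5 ± 8.996 to 157 ± 24.0 CPM (edgeR adjusted p = 0.00437). The others were Smyd3 (log2 fold change 0.70), Lcp2 (1.02), Tst (0.81), Magee2 (0.70), AW551984 (0.78), A730046J19Rik (1.06) and AI506816 (3.55). Tubb2b and Arhgap26 passed in all 8 fits without 1 library, and Lcp2, Tst and Magee2 in 1 each.

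AI506816, a processed transcript that overlaps Mir3096, was at 5.24, 8.08 and 6.84 CPM in KO replicates 1, 2 and 4 and at 0.643 CPM in KO replicate 3, within the Control range of 0.224 to 0.719 CPM. Fndc3c1 was at 13.0 CPM in KO replicate 2 and between 2.30 and 4.13 CPM in the other KO libraries. Cga, the shared subunit of pituitary glycoprotein hormones, was at 60.8 CPM in KO replicate 2 and at 0 to 6.18 CPM in the other 7 libraries, and Pomc was at 97.3 CPM there. Xist was at 2.41 ± 0.931 CPM in KO and 1.44 ± 0.265 in Control (log2 fold change 0.74, edgeR adjusted p = 0.516).

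Of the 40 called genes, 7 had another called gene within 1000 kb, in 5 pairs, of which 3 moved in the same direction, against a mean of 2.48 in 10000 random gene sets matched on expression. The 7 lay above that mean but within the central 95% of the random sets, whose upper end is 8 (one-sided permutation p = 0.0361). Chance placement thus stays open, and the test does not settle it. DNA linked to the floxed allele is argued against as the reason for the pairs, since 0 of them lay within 10 Mb of Cic, where 2 of 275 tested genes were called (Spred3 and Proser3, exact hypergeometric p = 0.155). This bears on the pairs alone, and linked DNA stays open for the calls of Spred3 and Proser3 themselves. Reads shared between overlapping neighbours are argued against, since 0 of the 5 pairs overlap; the pairs include Camk1g and Hsd11b1, 82.3 kb apart, and Arhgap26 and Spry4, 392 kb apart. No biological explanation was tested. By chromosome, 6 called genes lay on chromosome 15 (1.56 expected) and 6 on X (1.42 expected), each at a Benjamini-Hochberg adjusted one-sided Fisher exact p of 0.0445 over 21 chromosomes.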
